A study of Homo sapiens with 6 samples.

How the data were processed

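Total RNA from 1205Lu melanoma cells was sequenced in 6 libraries, 3 from flasks transfected with a SOX10 expression plasmid and 3 from flasks with the empty plasmid. Per the labels' protocols, each flask received 7.8 µg of plasmid DNA, cells were lysed 24 h later, and each library was made from 125 ng of total RNA with a NuGEN Encore Complete kit. The submitters' processing notes name TopHat 1.4.0, HTSeq, DESeq and the genome build hg19. The gene annotation, the strand setting and the overlap mode of the counting are not given in the sources used here.

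The values deposited by the authors are whole-number read counts per gene symbol, not normalized, for 23368 genes in 1 column per library. The table ends with 5 class rows of htseq-count that name no gene. They were left out of library sizes and tests. Reads outside any gene made up 39.4% to 46.9% of all counted records, reads in more than 1 place 17.7% to 19.1% and ambiguous reads 0.435% to 0.551%, and the rows for low quality and unaligned reads hold 0. Per 100 assigned reads, there were 93.5 reads outside genes in SOX10 replicate 1 and 97.0 in control replicate 3, against 121 to 135 in the other 4 libraries. Assigned reads ranged from 867917 to 4167393 per library. A count of 0 allows up to 3 reads, or 0.72 to 3.46 CPM, and such floors cover counting error only. The median standard error of a log2 fold change was 0.23.

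Each column was matched to its sample by the sample's title, and the group was taken from the treatment label. All pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 2.11 to 7.03. The replicate numbers in the titles are shared between groups. They were not used as pairs in the main test.

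The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on the counts of all 6 libraries, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and no covariate. P-values were adjusted by Benjamini and Hochberg over 10678 genes, with a threshold of 0.05. Log2 fold changes are SOX10 against control as fitted with edgeR's prior count of 0.125, standard errors were derived from the F statistic, and CPM are scaled by TMM. The common biological coefficient of variation was 12.7%. On counts simulated for this comparison from the real means and depths, run on 10487 genes, the test recovered 66 of 100 genes changed by 2-fold and 95 of 100 changed by 4-fold, with 12 false calls. The simulated genes varied independently of each other, and far more of them were changed than the 12 called in the data. These rates may thus not hold for the real comparison, where recovery may be lower.

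The design, the rule for named genes and 14 gene lists were fixed before the data were examined. The lists are SOX10 targets and myelin, pigment cell differentiation, neural crest regulators and receptors, invasive and mesenchymal state, interferon response, inflammatory NF-kB response, unfolded protein and amino acid stress, p53 targets, cell division, sterol and fatty acid synthesis, extracellular matrix and collagens, immediate early genes, and markers of keratinocytes and epithelia and of leukocytes and endothelium. SOX10 is in none. Lists with at least 5 tested genes (12 of 14) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Beside it stand camera with an estimated correlation and fry, with its directional test and its mixed test for changes in either direction. None of the 3 lists called by camera was called with an estimated correlation or by the directional test of fry.

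The rule for named genes takes SOX10, PMP2, up to 6 genes with the largest rise and the 6 with the largest fall among called genes of at least 1 CPM whose groups did not overlap, and the tested genes with the smallest p in each list, 4 in the first 2 lists and 2 in the others. Of the genes it names, 1 is not reported here. Alternatives planned in advance were other scalings (DESeq2 size factors, library totals, upper quartile, SOX10 left out of the totals), other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library. Added after the data were seen were thinning to equal depth, the ratio of reads outside genes as a covariate, an offset for GC content and length from GENCODE release 29 transcripts (available for 91.4% of tested genes), and leaving out SOX10 replicate 1 with control replicate 3. The reference used is of another build than hg19, so no coordinates are given.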

Results

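RNA sequencing measured gene expression in 1205Lu cells, an established human melanoma line. The cells were transfected either with a plasmid for expression of SOX10, a transcription factor of the neural crest, melanocytes and Schwann cells, or with the empty plasmid. They were harvested 24 h later, with 3 biological replicates per group. The series asks how SOX10 acts on gene expression in melanoma cells and names PMP2, a fatty acid binding protein of peripheral myelin, as the gene of interest. The libraries were shallow and the groups differed in depth. Reads assigned to genes numbered 3732799, 2544420 and 4167393 in the SOX10 libraries and 925578, 867917 and 2066520 in the control libraries. Every SOX10 library was thus deeper than every control library, and the ratio of the mean totals was 2.71. A single read was worth between 0.24 and 1.15 CPM (counts scaled to the library total), and 10678 of 23368 genes had enough reads for a test.

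The overexpressed gene itself was compared first, as a check of the labels. SOX10 stood at 25.02 ± 8.45 CPM (SD, n = 3) in the libraries labelled SOX10 and 19.6 ± 2.63 CPM (SD, n = 3) in the controls. The log2 fold change was 0.35 (SE 0.27), and the edgeR quasi-likelihood test gave an adjusted p of 0.927. The libraries labelled SOX10 had 81, 47 and 143 SOX10 reads, and the controls 15, 18 and 44. The 95% confidence interval of the fold ended at 1.87, so a larger rise in counted SOX10 reads lay outside it, and the labels could not be checked from SOX10 reads. Most of the difference came from SOX10 replicate 3, without which the log2 fold change was 0.030. Gene counts do not separate reads of the plasmid from those of the endogenous gene.

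PMP2 rose from close to no reads to a moderate level in all 3 libraries labelled SOX10. It stood at 21.3 ± 3.64 CPM (SD, n = 3) against 1.03 ± 0.98 CPM (SD, n = 3) in the controls. This was a log2 fold change of 3.99 (SE 0.49), or 15.9-fold with a 95% confidence interval from 7.90 to 31.9, and the adjusted p by edgeR was 0.000103. The rise rested on 66, 53 and 103 reads against 0, 1 and 4, and the log2 fold change was 5.12 without control replicate 3. The related gene FABP5, which encodes another fatty acid binding protein, had a log2 fold change of 0.24 (SE 0.38) and an adjusted p of 0.957. No exonic base of PMP2 was shared with another gene in GENCODE release 29.

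PMP2 was the only gene that rose, while 11 genes fell, out of 10678 tested with edgeR's quasi-likelihood test at an adjusted p under 0.05. In all 12 the 3 libraries of one group lay outside the range of the other. That held for 11.8% of all tested genes, against 10% by chance for 3 against 3. At an unadjusted p under 0.05 the test found 665 genes, which is 6.23% of those tested. NR1D1, a nuclear receptor that represses clock genes, fell by 1.83 on the log2 scale (SE 0.23), from 138 ± 63.6 to 38.3 ± 9.88 CPM (SD, n = 3 each). THRA, which shares 9.49% of the exonic bases of NR1D1 on the opposite strand in GENCODE release 29, had a log2 fold change of -0.38 (SE 0.42) and an adjusted p of 0.932. The antisense transcript H1FX-AS1 fell by 1.79 (SE 0.26), from 32.5 ± 5.51 to 9.08 ± 0.97 CPM. Its partner H1FX had a log2 fold change of -0.56 (SE 0.37) and an adjusted p of 0.913. The strand setting of the counting is not given in the sources used here, so reads of these opposite-strand pairs may not have been separated, and their values are uncertain to that extent. IL8, a chemokine for neutrophils, fell by 1.34 (SE 0.22), from 222 ± 84.4 to 90.2 ± 30.6 CPM. TNFAIP3, a feedback inhibitor of NF-kB, fell by 1.33 (SE 0.27), from 27.2 ± 8.02 to 11.3 ± 1.47 CPM. KLF10, a transcription factor induced by TGF-beta, fell by 1.10 (SE 0.17), and PPP1R15A, which directs the dephosphorylation of eIF2-alpha, fell by 1.08 (SE 0.13). Adjusted p-values of these 6 by edgeR ran from 0.000103 for NR1D1 and PPP1R15A to 0.0499 for TNFAIP3. The remaining called genes, named after their values were seen, were TIPARP, an ADP-ribosyltransferase, TXNIP, an inhibitor of thioredoxin, BHLHE41, a repressor of the clock, ZC3HAV1, an antiviral RNA-binding protein, and the stress transcription factor ATF3. TIPARP had the smallest p of all genes and fell by 1.01 (SE 0.12), from 630 ± 138 to 312 ± 10.1 CPM. Leaving out control replicate 1 reduced the 12 calls to 6, and 6 to 9 of the 12 remained without any single library. PMP2, NR1D1, H1FX-AS1, KLF10, PPP1R15A and TIPARP stayed called in each of these fits. IL8 had an adjusted p by edgeR of 0.144 without control replicate 1 and 0.138 without control replicate 3. By DESeq2 it was 0.635, the highest over all alternatives. The lowest, 4.01e-20, came from the fit with no low-count filter, and the next, 1.28e-05, from that with reads outside genes as a covariate. Among the fits without a single library, TNFAIP3 kept its call only in that without control replicate 2. Its adjusted p-values by edgeR ran from 0.0694 to 0.699 in the other 5 of these fits. ATF3 was called only without control replicate 3, ZC3HAV1 in none of these fits, BHLHE41 only without SOX10 replicate 1 or control replicate 3, and TXNIP in all but those without SOX10 replicate 3, control replicate 1 or control replicate 2. Without SOX10 replicate 1 and control replicate 3, the pair with the fewest reads outside genes per 100 assigned reads, 7 calls remained, all among the 12.

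**Figure D1:**
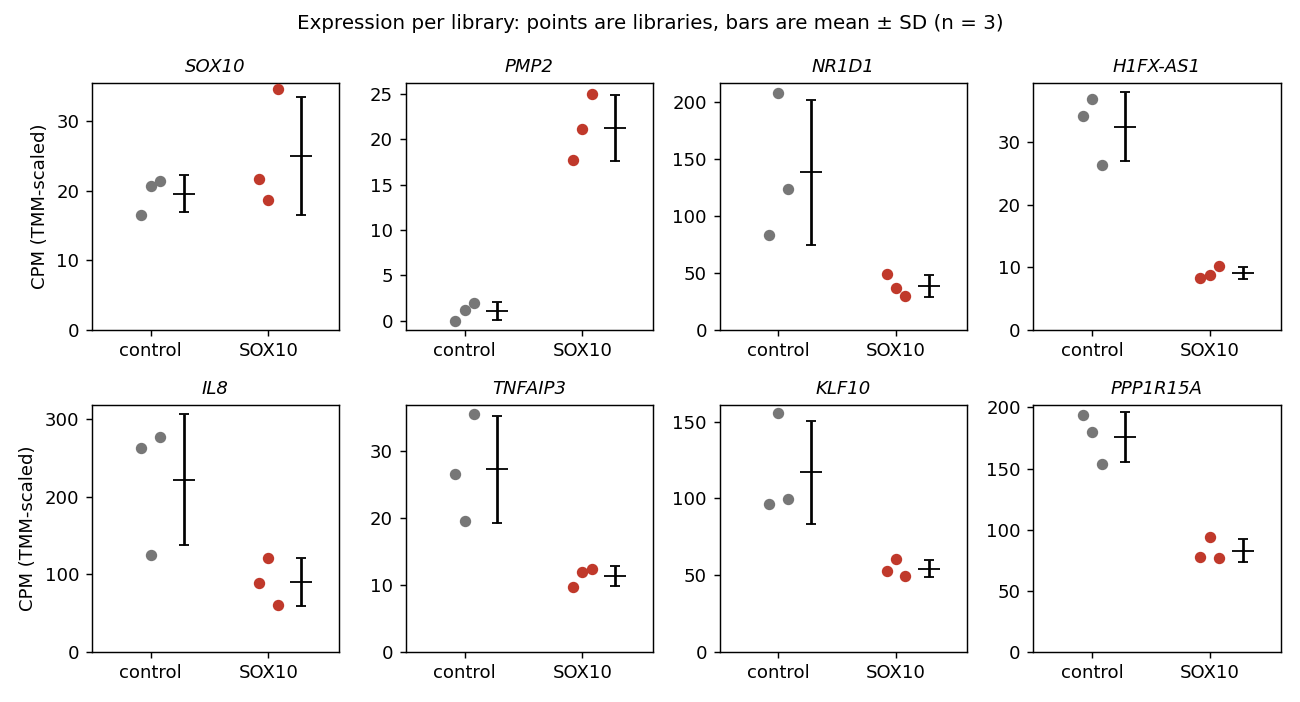
Expression in CPM (linear y axis, TMM-scaled) of SOX10, PMP2 and the 6 genes with the largest falls, with one point per library and the mean ± SD of 3 libraries beside it, for control and SOX10 groups. SOX10 overlaps between groups, PMP2 lies at 17.7 to 24.9 CPM against 0 to 1.95 CPM, and the other 6 genes are lower in all 3 SOX10 libraries.

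Apart from PMP2, no gene of the list of SOX10 targets and myelin genes passed the test. Of the 40 genes in the list 16 had enough reads, 1 rose and 0 fell, both over all genes and adjusted over the list alone. The other 15, of which none passed at an unadjusted p under 0.05 either, had a mean log2 fold change of 0.11 and ranged from -0.22 to 0.98. Adjusted over the list alone, 2 of 17 tested members rose without control replicate 2. The endothelin receptor gene EDNRB had a log2 fold change of 0.98 (SE 0.62) on 29, 9 and 19 against 1, 6 and 3 reads, which was 0.45 without control replicate 3 and 1.97 without control replicate 2, and NDRG1, mutated in a hereditary neuropathy, -0.22 (SE 0.12). For the whole list the mean was 0.35, with an adjusted p of 0.336 by camera, and 0.566 with an estimated correlation. The mixed test of fry, which asks for changes in either direction, had an adjusted p of 0.00293 with PMP2 in the list. Several genes of the list were already abundant in control cells. S100B stood at 307 ± 42.5 CPM and ERBB3 at 444 ± 36.6 CPM (SD, n = 3 each), with log2 fold changes of 0.05 (SE 0.12) and -0.02 (SE 0.12). These 2 genes were named after their values were seen.

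No pigment cell gene passed the test, and the levels of the tested members differed widely. Of 34 genes 11 were tested, with 0 higher and 0 lower by edgeR over all genes and adjusted over the list alone, 0 at an unadjusted p under 0.05, a list mean of 0.019 and an adjusted p of 0.606 by camera. MITF, the master regulator of melanocytes, stood at 4.80 ± 0.59 against 5.94 ± 2.46 CPM (SD, n = 3 each), with a log2 fold change of -0.44 (SE 0.46). MLPH, a melanosome transport protein, had -0.46 (SE 0.35), and the amino acid transporter SLC7A5, at 228 ± 17.6 against 255 ± 17.2 CPM, had -0.17 (SE 0.11). Without control replicate 3 the values of MITF and MLPH were 0.078 and 0.14. The pigment enzymes TYR and DCT were too rare for the test, with 9 and 6 reads over all 6 libraries, and MLANA had 4 reads. Falls or small changes in these genes were not detectable at this depth.

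Neither neural crest nor invasion genes were called as groups in one direction by camera, while the mixed test of fry had an adjusted p of 0.010 for the neural crest list and 0.0236 for the invasive list. Of 21 tested neural crest regulators and receptors none passed over all genes by edgeR, 3 had an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. This was NGFR, the low-affinity nerve growth factor receptor, at 1.84 ± 0.56 against 8.05 ± 3.34 CPM (SD, n = 3 each), with a log2 fold change of -1.94 (SE 0.54) and an adjusted p of 0.292 over all genes. It rested on 8, 3 and 9 reads in the SOX10 libraries. The call over the list alone was lost with limma-voom, with the CPM filter, with the replicate number as a block and without any single library except control replicate 3. After thinning, NGFR was not among the 16 genes of the list that were tested. In the alternatives that tested NGFR, its log2 fold change ran from -2.40 to -1.63. SOX9, a related transcription factor, had -0.24 (SE 0.11). The list's median was 0.013 and its mean -0.10, with an adjusted p of 0.462 by camera. Of 35 tested genes of the invasive and mesenchymal list 0 passed over all genes by edgeR, 6 had an unadjusted p under 0.05, and 2 rose and 2 fell adjusted over the list alone. These counts were 0 and 0 without SOX10 replicate 3, control replicate 1 or control replicate 3, with the replicate number as a block and after thinning. They were 0 and 1 without SOX10 replicate 2 or control replicate 2. CDH2, or N-cadherin, had a log2 fold change of 0.39 (SE 0.11) with an adjusted p of 0.333 by edgeR over all genes, and JUN -0.60 (SE 0.17) with 0.305. Their mean was -0.038 and the adjusted p by camera 0.606.

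With its preset correlation, camera called 3 of 12 tested lists as lower in the SOX10 libraries, namely inflammatory NF-kB genes, p53 targets and immediate early genes. None of these calls held with the correlation estimated, at adjusted p = 0.566 with an estimated correlation for the NF-kB list and 0.177 for each of the other lists. Of 17 tested NF-kB genes 16 had a negative log2 fold change. IL8 and TNFAIP3 fell over all genes, and 10 fell adjusted over the list alone by edgeR. Over all genes 0 fell without control replicate 1 or 3, 1 without SOX10 replicate 2 or 3, 4 without SOX10 replicate 1 and 6 without control replicate 2. Adjusted over the list alone 4 fell without control replicate 3, 6 without SOX10 replicate 3 and 4 with DESeq2. The list mean was -0.75 and the adjusted p by camera 2.06e-06, but adjusted p = 0.566 with an estimated correlation. That estimate of the correlation between members was 0.68. The mean level of the list overlapped between groups, with control replicate 2 below SOX10 replicates 1 and 2. Without control replicate 3 the list mean was -0.36 and the adjusted p by camera 0.0169. Without SOX10 replicate 1 and control replicate 3 the list mean was -0.58 and the adjusted p by camera 0.0001, while 0 members passed over all genes and 6 did adjusted over the list alone. The mixed test of fry had an adjusted p of 0.195 for the NF-kB list. For the interferon, pigment cell, cell division, sterol and matrix lists it ran from 0.596 to 0.819.

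Of 20 tested p53 targets 17 had a negative log2 fold change, yet 0 passed the edgeR test over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. Adjusted over the list alone 1 fell without control replicate 3. The DNA damage gene GADD45A had -0.48 (SE 0.17) and the ribonucleotide reductase subunit RRM2B -0.43 (SE 0.17). Their list had a mean of -0.34, with an adjusted p of 2.32e-06 by camera and adjusted p = 0.177 with an estimated correlation. Of 24 tested immediate early genes 19 had a negative log2 fold change. ATF3 fell over all genes by 0.86 (SE 0.17), with adjusted p-values by edgeR from 0.0386 to 0.469 without single libraries, and 5 genes fell adjusted over the list alone, which became 2 without control replicate 3 and 2 after thinning. JUNB, a subunit of AP-1, had -0.79 (SE 0.21) with an adjusted p of 0.245 by edgeR over all genes. The mean of the list was -0.28, with an adjusted p of 0.000147 by camera and adjusted p = 0.177 with an estimated correlation. Both lists had a higher mean level in each control library than in each SOX10 library, and the mixed test of fry had an adjusted p of 0.00705 for p53 targets and 0.00293 for immediate early genes. After thinning to equal depth, a setting chosen after seeing the data, the means were -0.23 for each list, with adjusted p-values by camera of 0.00464 and 0.0145.

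**Figure D2:**
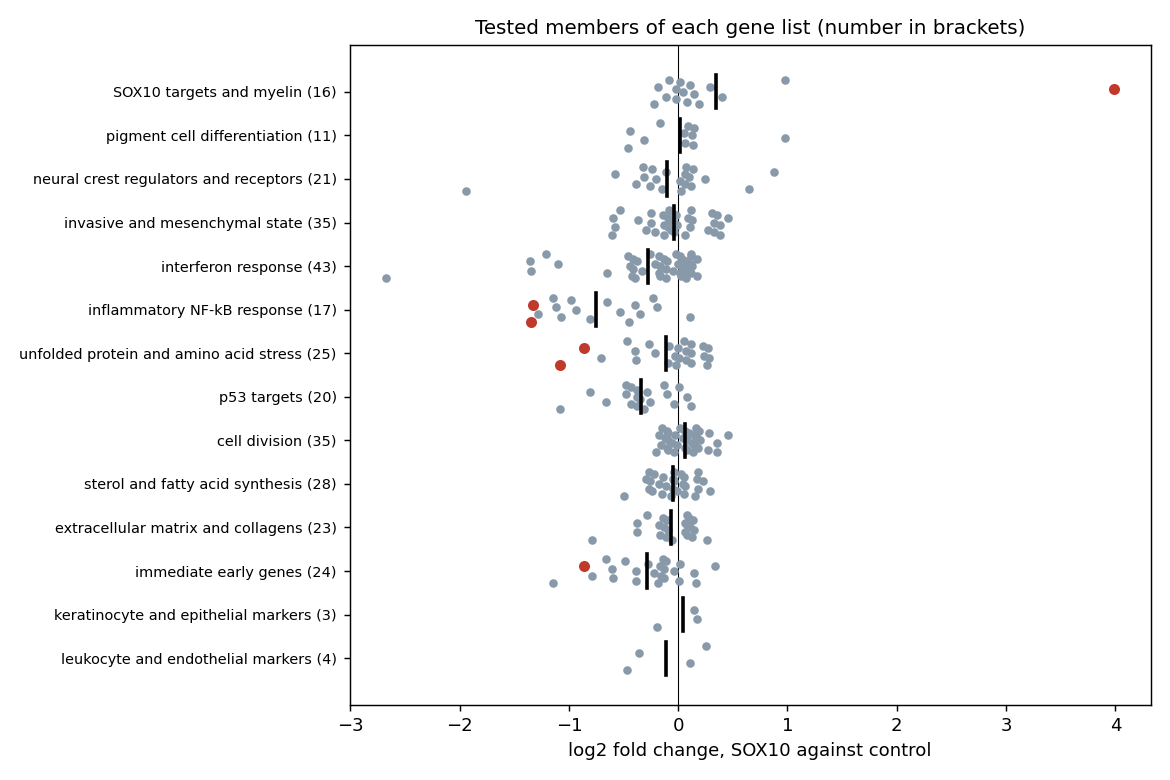
Log2 fold change (x axis, SOX10 against control) of each tested member of the 14 gene lists (y axis), with large red points for genes at an adjusted p under 0.05 and a black bar at the list mean. PMP2 stands alone at 3.99, and the inflammatory NF-kB, p53 and immediate early lists have means of -0.75, -0.34 and -0.28.

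The interferon list was not called between groups. All 43 genes were tested, 0 passed over all genes, 7 had an unadjusted p under 0.05 and 4 fell adjusted over the list alone by edgeR. The last count was 13 without SOX10 replicate 1 and 11 without control replicate 2, with 2 falls over all genes in each of these fits, and 0 without any other single library. The interferon gene IL29 stood at 0.87 ± 0.95 against 6.44 ± 2.18 CPM and the chemokine CCL5 at 32.8 ± 19.6 against 79.8 ± 47.0 CPM (SD, n = 3 each), with log2 fold changes of -2.67 (SE 0.67) and -1.36 (SE 0.34). Both had an adjusted p of 0.215 by edgeR over all genes, and for CCL5 it was 0.00592 without SOX10 replicate 1 and 0.00976 without control replicate 2. Without any other single library it ran from 0.545 to 0.792. The log2 fold change of CCL5 was -1.99 without SOX10 replicate 1 and -0.88 without control replicate 3. Over the list the mean was -0.28 and the adjusted p by camera 0.0821, with adjusted p = 0.796 with an estimated correlation. Without SOX10 replicate 1 the mean was -0.46 and without control replicate 2 it was -0.41, both past the threshold of camera. It was -0.15 without SOX10 replicate 3 and -0.076 without control replicate 3. After thinning the mean was -0.13 with an adjusted p of 0.444 by camera. Means per library ranged more widely within groups than the groups differed, from -0.28 to 0.40 in the controls and from -0.37 to 0.17 in the SOX10 libraries on the log2 scale.

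**Figure D3:**
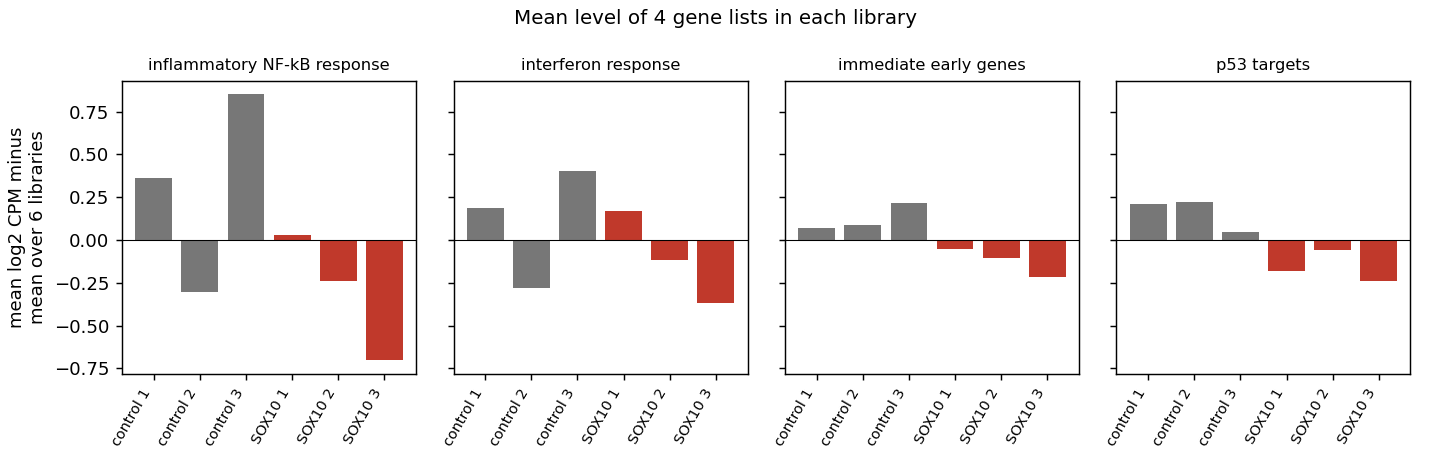
Mean log2 CPM of 4 gene lists in each library, as the difference from the mean over the 6 libraries (y axis, log2 units), with control libraries in grey and SOX10 libraries in red. The inflammatory and interferon lists overlap between groups, whereas the immediate early and p53 lists are higher in all 3 controls.

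Of 25 tested genes of the unfolded protein and amino acid stress list 2 fell by edgeR over all genes, PPP1R15A and ATF3, and 3 adjusted over the list alone. The group mean was -0.11 with an adjusted p of 0.374 by camera and 0.0144 by the mixed test of fry. Of 35 cell division genes 0 passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, with a list mean of 0.064 and an adjusted p of 0.462 by camera. Cyclin D1 (CCND1) had a log2 fold change of -0.17 (SE 0.09) and the replication factor MCM4 0.16 (SE 0.09). Of 28 genes of sterol and fatty acid synthesis 0 passed either way and 1 had an unadjusted p under 0.05, with a list mean of -0.051 and an adjusted p of 0.606. CYP51A1 of the sterol pathway had -0.30 (SE 0.14), and ACACA, which makes malonyl-CoA for fatty acids, 0.29 (SE 0.15), or 0.19 without control replicate 3. Of 23 matrix and collagen genes 0 passed either way and 0 had an unadjusted p under 0.05, with a list mean of -0.068 and an adjusted p of 0.606. COL4A1 had 0.26 (SE 0.13), or 0.13 without control replicate 3, and COL6A3 -0.79 (SE 0.54), or -0.49 without SOX10 replicate 2 and -1.31 without SOX10 replicate 3. DESeq2 and limma-voom also called 0 genes over all genes in each list for which edgeR called 0. Markers of other cells were mostly too rare for a test. Of 20 keratinocyte and epithelial markers 3 were tested, and of 22 leukocyte and endothelial markers 4. None passed or had an unadjusted p under 0.05, with log2 fold changes of 0.18 (SE 0.16) for DSP, 0.15 (SE 0.18) for KRT18, -0.36 (SE 0.24) for CD68 and 0.26 (SE 0.24) for FLT1. Leaving out single libraries moved these values widely. CD68, at 353 ± 149 against 443 ± 184 CPM (SD, n = 3 each), ranged from -0.67 without SOX10 replicate 1 to -0.010 without control replicate 3. FLT1 ranged from 0.52 without control replicate 1 to 0.044 without control replicate 3, DSP from 0.25 without control replicate 1 to 0.083 without SOX10 replicate 3, and KRT18 from 0.21 without control replicate 2 to 0.095 without control replicate 1. Adjusted over the list alone, 1 leukocyte or endothelial marker fell without SOX10 replicate 1 and 1 without control replicate 2. Without control replicate 3, 1 of 4 tested keratinocyte and epithelial markers fell, and their list mean was -0.71.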

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

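PMP2 passed the threshold in all 19 alternative fits, with log2 fold changes from 3.61 to 5.22, and SOX10 passed in none, from 0.030 to 0.55. The 0, 1 and 4 PMP2 reads of the controls limit how well its fold is known. The 12 changed genes (1 higher, 11 lower) became 48 (13 and 35) with no low-count filter and 7 (1 and 6) with the replicate block, under which IL8, BHLHE41, ZC3HAV1, ATF3 and TNFAIP3 were lost. Deviations from the group means over 3126 genes correlated at -0.12, -0.076 and -0.42 between same-numbered libraries. No SOX10 library correlated best with the control of its own number. The highest correlations were 0.50 for SOX10 replicate 1 with control replicate 3, 0.22 for SOX10 replicate 2 with control replicate 1 and 0.43 for SOX10 replicate 3 with control replicate 2. With 3 libraries per group these correlations are not independent, so a pairing by number was not seen but is not ruled out. The count was 43 (9 and 34) with the share of reads outside genes as a covariate and 7 (1 and 6) without SOX10 replicate 1 and control replicate 3, and these settings, thinning and the GC and length offset were chosen after seeing the data. Higher genes alone became 2 with library totals, 3 with the filter of CPM of at least 1 in 3 libraries, 2 after thinning and 3 with the GC and length offset. Lower genes became 7 with upper-quartile scaling and 7 with limma-voom. Leaving out single libraries gave 6 to 18 changed genes, 1 to 4 higher and 5 to 16 lower, with the lowest count without control replicate 1 and the highest, 18, without SOX10 replicate 1 and without control replicate 2. The covariate and GC fits and the fit without a filter also called ICAM1 and CXCL1. So did the fits with the CPM filter, without SOX10 replicate 1 and without control replicate 2. CXCL1 was called with library totals too. DESeq2 called 11 genes. The interferon list passed with DESeq2 (mean -0.26), limma-voom (-0.32), the covariate (-0.33) and the offset (-0.30), but not after thinning (-0.13, adjusted p 0.444) or without SOX10 replicate 1 and control replicate 3 (-0.16, adjusted p 0.48), and, over left-out libraries, its mean ran from -0.46 to -0.076. The inflammatory list (-0.75), p53 targets (-0.34) and immediate early genes (-0.28) lost the call with an estimated correlation and with the directional test of fry, at the same mean, and kept it in the 19 other fits. Those 19 fits all used camera with the preset correlation, so they do not speak to the setting on which the calls were lost. Uncalled lists changed sign without a filter (neural crest 0.21, matrix 0.32) and with the CPM filter (matrix 0.16), and over left-out libraries pigment ran from -0.11 to 0.086, invasion from -0.092 to 0.016 and sterol synthesis from -0.14 to 0.085. The uncalled genes MLPH, from -0.71 to 0.14 over left-out libraries and 0.081 without SOX10 replicate 1 and control replicate 3, and MITF, from -0.59 to 0.078, also changed sign. Over left-out libraries the mean of the cell division list ran from 0.025 to 0.16 and that of the unfolded protein list from -0.17 to -0.058. The matrix mean ran from -0.20 to -0.037 and the neural crest mean from -0.14 to -0.054, and none of these lists was called. The cause of these shifts was not tested.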

Other observations

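Tests of an exchanged library, of ambiguous reads, of the spread of the inflammatory list and of other splits for the gene count were chosen after the results were seen, as were the genes of the next sentences, the clock genes as a topic and the sign test on them, and the settings for depth and for GC content. The outcomes of these 2 settings had not been seen when their tests were written. Some interferon-stimulated genes were abundant in both groups 24 h after transfection, while others, such as BST2 at 29.3 against 35.4 CPM, were not. IFIT1, an antiviral RNA-binding protein, stood at 2502 ± 27.6 CPM in the SOX10 libraries and 2451 ± 336 CPM in the controls (SD, n = 3 each), with a log2 fold change of 0.03 (SE 0.09). The antiviral GTPase MX1 stood at 1192 ± 94.0 against 1099 ± 13.7 CPM and OAS1, which makes the activator of RNase L, at 547 ± 42.4 against 502 ± 43.4 CPM, with log2 fold changes of 0.12 (SE 0.09) and 0.12 (SE 0.10). No untransfected cells were analysed here. FAT4, a protocadherin, came closest to a second rise, at 17.1 ± 4.14 against 4.64 ± 0.23 CPM, with a log2 fold change of 1.84 (SE 0.38) and an adjusted p of 0.0514 by edgeR. It was called with library totals, with no filter, with the CPM filter, without SOX10 replicate 1, after thinning, with the covariate and with the GC and length offset. The nuclear RNA MALAT1 had -0.44 (SE 0.09) and an adjusted p of 0.077, and was called with no filter, with the CPM filter, without control replicate 2, after thinning, with the covariate and with the offset.

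SOX10 reads were not clearly higher in the libraries labelled SOX10, while PMP2 was 15.9-fold higher. PMP2 speaks against an exchange of a SOX10 with a control library only if PMP2 follows the plasmid, which the SOX10 reads could not show. The separation of PMP2 between the groups was also known before this test was chosen. For PMP2 the lowest SOX10 library exceeded the highest control by 9.06 times, with an exact 95% interval from 3.38 to 34.2 that covers counting error only. A loss of SOX10 reads to the ambiguous class stays open. Ambiguous reads made up 1.27% to 1.31% of assigned and ambiguous reads in the SOX10 libraries and 1.24% to 1.27% in the controls. The share of SOX10 replicate 2 was below that of control replicate 1. Such totals do not show which genes the reads came from. In GENCODE release 29 only 2.40% of the exonic bases of SOX10 are also exonic in another gene (POLR2F), but the annotation used for counting is not given in the sources used here. A low share of transfected cells, or an effect of SOX10 on PMP2 without more counted SOX10 reads, was not tested.

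The inflammatory NF-kB list had a mean log2 fold change of -0.75 in the SOX10 libraries. After thinning every library to 867917 reads the mean over 15 tested members was -0.73. The adjusted p was 1.00e-06 by camera with the preset correlation. Random thinning leaves expected ratios unchanged, so a mean near -0.75 was likely beforehand. Thinning speaks to read number alone and cannot address differences between the groups that accompany depth. A trend with GC content and length that differs between the groups is argued against, since with the offset the mean was -0.76. The adjusted p was 1.71e-06 by camera with the preset correlation. Single libraries did show trends. Their rank correlations with GC content ran from -0.31 to 0.37 in the SOX10 libraries and from -0.11 to 0.20 in the controls. These ranges overlap, so little change of the mean was likely beforehand. A variation between libraries that does not follow the plasmid is a candidate explanation, put forward after its values were known. Differences between cultures and between library preparations cannot be told apart here. The list's estimated inter-gene correlation was 0.68, its adjusted p with that correlation was 0.566, and the groups overlapped. An effect of SOX10 on part of the list stays open.

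Of the 10 splits of the 6 libraries into 3 and 3, 2 gave at least 12 changed genes, and with 10 splits no share under 0.05 can be reached. The highest other split, SOX10 replicate 1 with controls 1 and 3 against the rest, called 69 genes, which points to a structure of the samples apart from the plasmid. These included 13 of the 43 tested interferon genes, 8 of the 17 inflammatory NF-kB genes, whose list mean was 0.92 in that split, and 6 HLA genes, of which HLA-B and HLA-F are also in the interferon list. The leukocyte marker CD68 was also called in that split, at a log2 difference of 0.93 (SE 0.15) and an adjusted p of 0.000211 by edgeR. Of the 12 genes called between the groups, 1 was among them, IL8. In number of lists called, 5 of the 10 splits reached at least the 3 of the real split, and the highest other number was 5. These calls use the preset correlation. In the split with 69 genes none held by camera with the correlation estimated, with adjusted p = 0.214 with an estimated correlation as the lowest. The directional test of fry did call the unfolded protein list in that split, with an adjusted p of 0.0327. The mixed test of fry had an adjusted p of 0.0486 there for both the interferon and the NF-kB list. The numbers of lists called do not say that the lists were the same. In the split with 69 genes p53 targets and immediate early genes were not called with the preset correlation, with adjusted p-values by camera of 0.764 and 0.0511.

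A hypothesis of a shifted circadian clock was raised by the falls of NR1D1 and BHLHE41. Of 11 other clock genes driven from E-boxes 9 were tested, 6 had a negative log2 fold change and 0 passed over all genes by edgeR. Their mean was -0.16 with a 95% interval over genes from -0.38 to 0.07, the list was not past the threshold of 0.05 by camera, and an exact two-sided sign test over these genes, which are not independent, gave p = 0.508. A shared fall as large as that of BHLHE41, -0.98, lies outside this interval, whereas a small one does not. The interval also treats these genes as independent and leaves out error between libraries, so it may be too narrow. A shift that moves clock genes in different directions was not tested.

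GH1, the growth hormone gene whose polyadenylation sequence many expression plasmids carry, had 19 of its 20 reads in control replicate 3, 1 in control replicate 1 and 0 in the SOX10 libraries.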
